A study of Homo sapiens with 14 samples.

How the data were processed

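CUT&RUN was done in U2OS cells with antibodies against BMI1, RNF2 and EZH2, in control cells and in cells with ORCA knocked down by siRNA given in consecutive rounds of 24 h each, per the labels' protocols. Cells were lightly fixed and 500000 were used per reaction, per the labels' protocols. The series has 14 samples. The 12 samples with a peak list form 6 groups of 2 replicates, and the 2 IgG samples were not used here. The labels do not say that replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

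The deposited files are peak lists in narrowPeak form, with 1 list per sample and no pooling of replicates, as their peak names show. Bowtie2, SAMtools, MACS2, bedtools, deepTools, DiffBind and DESeq2 are named in the submitters' processing notes, without roles, order or versions. Whether the IgG libraries served as background for peak calling, the filters and the peak caller's settings are not given in the sources used here. Per the deposited lists, each peak has an integer score, a fold enrichment over local background (a ratio), a -log10 p-value and a -log10 q-value, all the authors' own, and a summit offset (another position value), which was not used. The smallest -log10 q-value over all deposited lists was 1.30, that is a q-value of 0.0500. Folds and -log10 q-values served to describe, rank or filter peaks within a list and were never compared as levels between lists, and the scores were not used. A threshold of this kind makes the length of a list depend on read depth and on the ratio of signal to background, neither of which the lists give. The lists have no spike-in scaling.

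The processing notes name hg38 and T2T-CHM13. The last peak on chromosome 9 ends at 150493497, beyond the last gene on that chromosome in the GRCh38 table at hand (138331809), so the lists are on T2T-CHM13. No annotation or sequence of that build was used here, and coordinates were not converted. The planned comparisons of promoters, gene lists and sequence context were therefore not run, and regions are named by position. The rule for named regions was fixed before the data were examined. It takes, per antibody, the 10 lost, 10 gained and 10 kept regions with the highest mean percentile of fold within their lists. The EZH2-rich domains, chromosomes and bins named in the text were chosen after their values were seen.

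Lists were read with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and intervals were merged when they touched. Exact intervals and Fisher's exact tests came from scipy 1.17.1 and figures from matplotlib 3.10.9. Only chromosomes 1 to 22 and X occur in the lists. Regions of an antibody are the merged peaks of its 4 libraries, and an overlap of 1 bp counted as shared. Reproducible regions have a peak in both libraries of a condition. Wide clusters are peaks merged within 3000 bp that span at least 10000 bp. Densely covered bins are the stretches of 1000000 bp in which every list covers at least 50000 bp. Bins with a mean coverage under 20000 bp were left out of the count of bins. No exclusion list of artefact regions was used here.

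Per library, the number of peaks, covered length, wide clusters, regions bound and overlap with other antibodies were compared by an exact permutation test, two-sided. Condition labels were permuted within each antibody over all 216 combinations, with the sum of the 3 differences of group means (log2, or percentage points for shares) as statistic. Its smallest p is 0.00926, and a single antibody cannot go below 0.333. Tests over chromosomes were adjusted by Benjamini-Hochberg. On independent normal values simulated for 3 antibodies with 2 against 2 libraries, 4.9% of 1000 null tests came out at or under 0.05. With a shift of 4 SD, 100% of 300 tests did. The simulation had no libraries that share a culture, so it gives no error rate for that case. On regions of a control BMI1 list, 100% of 200 removed regions were found. The definition of lost regions fixed that outcome, so it checked only the computation and gives no rate of false calls.

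The labels give a batch for each library, which is the same for same-numbered control and siORCA libraries except RNF2 replicate 2, where the siORCA library is in batch 3. The replicate numbers therefore pair 5 of 6 pairs by batch. As a check, differences between the replicates over 877 bins correlated between control and siORCA at 0.125 for BMI1, 0.101 for RNF2 and 0.189 for EZH2. A sign-flip test over the 6 pairs has 64 patterns and a smallest p of 0.0312. Control EZH2 replicate 2 carries peak names of replicate 1 inside its list, and it shared only 13 peaks with identical ends with replicate 1, so both were kept as separate samples.

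Alternatives fixed before the data were examined were a -log10 q of at least 5, lists limited to the 61479 peaks with the highest -log10 q, an overlap of at least 50% of the shorter interval, merging within 500 bp, clusters within 5000 bp spanning 20000 bp, same-numbered pairs, batch 1 alone, and leaving out each library. Leaving out the densely covered bins and other definitions of the EZH2-rich domains were added later, as were same-numbered pairs for the chromosome shares and bins. With the 50% overlap, lost and gained regions were counted on the peaks of the first replicate.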

Results

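The series maps 3 Polycomb proteins in U2OS cells, a human osteosarcoma cell line, with and without ORCA, a protein that binds the origin recognition complex and heterochromatin. BMI1 and RNF2 belong to Polycomb repressive complex PRC1, which ubiquitinates histone H2A, and EZH2 is the methyltransferase of Polycomb repressive complex PRC2. Binding was profiled by CUT&RUN, in which an antibody directs a nuclease to the sites it binds and the released DNA is sequenced. Each antibody was used in 2 control libraries and 2 libraries of cells treated with siRNA against ORCA (siORCA), which gives 12 peak lists. The series also has 2 IgG samples, which were not used here. The lists held between 61479 peaks (control EZH2 replicate 1) and 106822 peaks (siORCA BMI1 replicate 2). Read depth is unknown because the lists hold no read counts, so no interval that needs it is given. The level of ORCA itself is not measured by these lists. All positions are on T2T-CHM13. Genes are not named, because the annotation at hand is on another build.

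The first comparison asked whether the number of called peaks differed between siORCA and control cells. This number depends on read depth and on signal to background, both unknown here, so it does not measure the amount of bound chromatin. More peaks were called after ORCA knockdown for all 3 proteins. BMI1 peaks numbered 66571 ± 3801 (SD, n = 2) in control and 91281 ± 21979 (SD, n = 2) in siORCA libraries, a ratio of 1.37. RNF2 peaks went from 79754 ± 7715 to 92729 ± 3166, a ratio of 1.16, and EZH2 peaks from 68026 ± 9258 to 92453 ± 4687, a ratio of 1.36. The size for BMI1 depends on single libraries, with a log2 change of 0.44 that became 0.19 without siORCA BMI1 replicate 2 and 0.68 without siORCA BMI1 replicate 1. The RNF2 change of 0.22 became 0.12 without control RNF2 replicate 2. Over the 3 antibodies the mean change was 0.37 on the log2 scale, with higher numbers in 6 of 6 same-numbered pairs (exact permutation test, two-sided, p = 0.00926, the smallest this test can give). Between the batch 1 libraries alone it was 0.29. Counting only peaks with a -log10 q of at least 5, the mean change was 0.24 (exact permutation p = 0.0185). Such counts were higher in 5 of 6 pairs (exact sign-flip p = 0.0625). For RNF2 they overlapped between the conditions, with a ratio of 1.09, against 1.24 for BMI1 and 1.22 for EZH2. The p-value takes the libraries as independent, although libraries of the same batch and condition may share a culture.

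**Figure D1:**
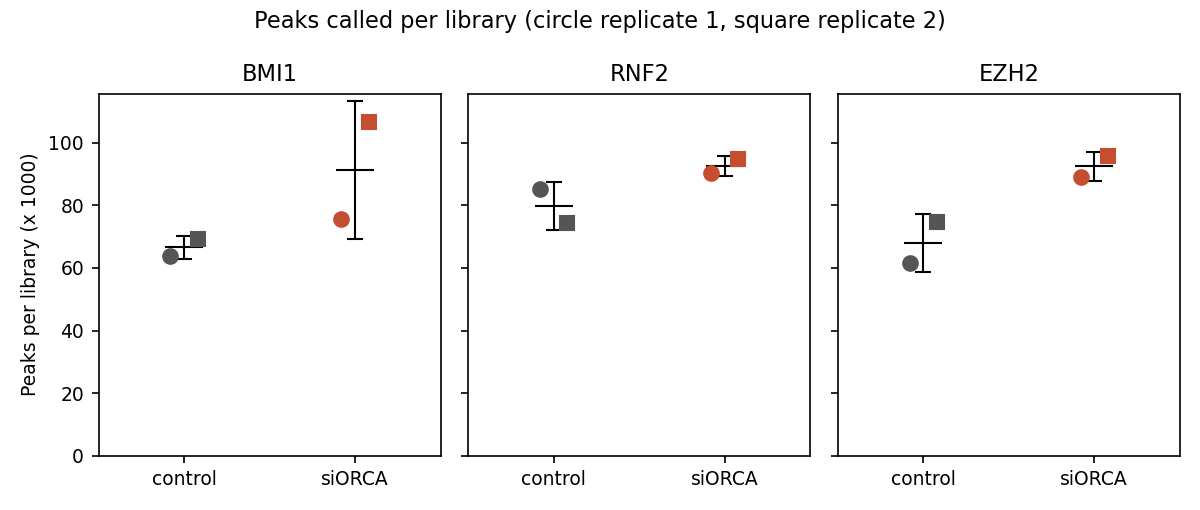
Number of peaks per library (axis in units of 1000 peaks) for BMI1, RNF2 and EZH2, with control libraries in grey and siORCA libraries in orange; the horizontal bar and whiskers give the mean and SD of 2 libraries. For each antibody both siORCA libraries lie above both control libraries.

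The length of genome covered by peaks moved less than their number. BMI1 peaks covered 55.1 ± 2.38 Mb in control and 66.8 ± 13.2 Mb in siORCA libraries, and EZH2 peaks covered 44.2 ± 2.60 and 53.6 ± 0.374 Mb. RNF2 coverage overlapped between the conditions, at 69.5 ± 5.52 and 74.0 ± 6.73 Mb. The BMI1 change of 0.26 (log2) became 0.059 without siORCA BMI1 replicate 2 and 0.47 without siORCA BMI1 replicate 1, and the RNF2 change of 0.091 became -0.0020 without siORCA RNF2 replicate 2. The mean change was 0.21 (log2; exact permutation test, two-sided, p = 0.0278), or 0.12 between batch 1 libraries. With same-numbered libraries as pairs, p was 0.0625, with 5 of 6 pairs higher. The change was -0.034 when every list was limited to its 61479 peaks with the highest -log10 q (exact permutation p = 0.370), and 0.0096 with a -log10 q of at least 5 (exact permutation p = 0.917). Leaving out control BMI1 replicate 1 or 2, control RNF2 replicate 2 or siORCA RNF2 replicate 2 gave p between 0.0648 and 0.0926.

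Polycomb proteins often spread over wide domains, and the number of wide peak clusters was compared next. Clusters of peaks within 3000 bp that spanned at least 10000 bp showed no common direction. EZH2 clusters numbered 781 ± 43.8 in control and 638.5 ± 85.6 in siORCA libraries, while BMI1 clusters numbered 552.5 ± 7.78 and 700.5 ± 151. RNF2 clusters overlapped between the conditions (763.5 ± 72.8 and 870.0 ± 132). Over the 3 antibodies the change was 0.071 (log2; exact permutation test, two-sided, p = 0.620). The BMI1 increase largely went with list length, since in equally long lists its log2 change was 0.059 instead of 0.33, that of RNF2 0.00011 instead of 0.18, that of EZH2 -0.69 instead of -0.30, and the mean -0.21. Single libraries mattered as well. Without siORCA BMI1 replicate 2 the BMI1 change was 0.10, without siORCA RNF2 replicate 2 the RNF2 change was 0.029, and without siORCA EZH2 replicate 2 the EZH2 change was -0.16. Single peaks of at least 10000 bp fell in number for EZH2 from 201 ± 12.7 to 102.5 ± 16.3, with both siORCA libraries below both control libraries. The corresponding numbers were 144.5 and 151 for BMI1 and 184 and 176 for RNF2, and over the 3 antibodies the test did not pass (log2 -0.33, exact permutation p = 0.167).

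The wide clusters of the EZH2 lists were then examined for where this loss lay. EZH2-rich domains were defined after the data had been seen. They are clusters of the pooled EZH2 peaks spanning at least 10000 bp, covered to a larger share by EZH2 than by the mean of BMI1 and RNF2, and to at least 25% by EZH2. These 526 domains spanned 20.1 Mb. Inside them all 3 proteins covered less after ORCA knockdown. EZH2 peaks covered 11.1 ± 0.375 Mb in control and 7.72 ± 0.791 Mb in siORCA libraries (n = 2 each), a ratio of 0.693. RNF2 went from 3.06 ± 0.233 to 2.09 ± 0.0543 Mb, a ratio of 0.682, and BMI1 from 2.31 ± 0.164 to 1.69 ± 0.214 Mb, a ratio of 0.729. The mean change was -0.51 (log2; exact permutation test, two-sided, p = 0.00926), with lower coverage in 6 of 6 pairs, and -0.54 between batch 1 libraries. In equally long lists it was -0.66.

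This result rests on how the domains were chosen. Over all 3360 wide clusters of the EZH2 lists, with neither condition on coverage, the mean change was -0.11 (log2; exact permutation p = 0.0926). EZH2 coverage was then 19.5 Mb in control and 16.4 Mb in siORCA libraries, BMI1 coverage 10.3 and 10.5 Mb, and RNF2 coverage 11.7 and 11.1 Mb. With the condition on the larger EZH2 share alone the change was -0.22 (exact permutation p = 0.0556), and with the 25% minimum alone -0.26 (exact permutation p = 0.00926). Wide clusters built from the BMI1 or RNF2 lists went the other way more often. Of 1783 BMI1 clusters, BMI1 coverage was lower in both siORCA libraries at 360 and higher at 741, and of 2372 RNF2 clusters, RNF2 coverage was lower at 598 and higher at 764. Of the 3360 EZH2 clusters, EZH2 coverage was lower at 976 and higher at 872. All these clusters came from the full lists, which were longer in siORCA libraries. The counts were not repeated in equally long lists, so they cannot be told apart from an effect of list length.

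**Figure D2:**
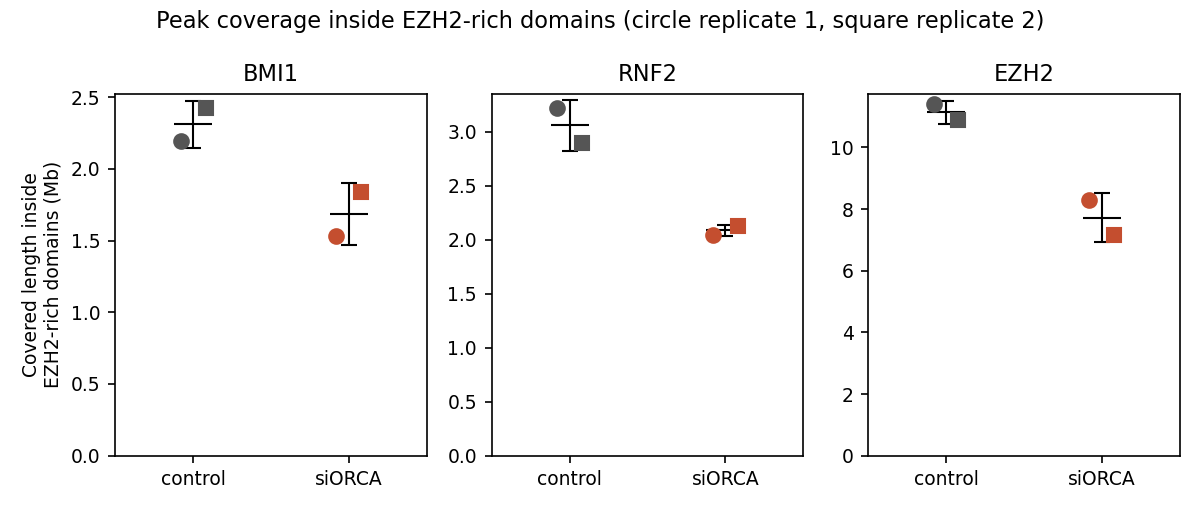
Length covered by peaks inside the 526 EZH2-rich domains, in Mb, for each library; axes differ between antibodies and start at 0, and bars and whiskers give the mean and SD of 2 libraries. Coverage in both siORCA libraries is below that in both control libraries for each antibody.

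Among the 526 domains, EZH2 coverage was lower in both siORCA libraries than in both control libraries at 429 and higher at 7. RNF2 was lower at 223 and higher at 70, and BMI1 was lower at 160 and higher at 74. With random labels and no ties, both siORCA libraries would lie on a given side in 16.7% of domains on average. Domains share their libraries and are not independent, so that share is only a guide. The domains were also defined on these lists after the data had been seen, so the counts above are not independent support. In the other splits of the 4 libraries of an antibody the highest one-way count was 39 for EZH2, 57 for RNF2 and 106 for BMI1. At 130 domains coverage was lower for all 3 proteins, and at 1 it was higher for all 3. Of the 30 domains with the most EZH2 coverage, 22 were lower for all 3 proteins.

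The domain with the most EZH2 coverage, on chromosome 8 from 142760484 to 143314659, had 430.4 ± 8.69 kb covered by EZH2 in control and 326 ± 32.7 kb in siORCA libraries. BMI1 there covered 56.7 ± 3.72 and 37.4 ± 1.45 kb, and RNF2 82.0 ± 6.08 and 55.4 ± 2.67 kb. On chromosome 11 from 113955833 to 114291103, EZH2 went from 243 ± 5.55 to 179.5 ± 11.8 kb, RNF2 from 143 ± 9.38 to 92.5 ± 3.83 kb and BMI1 from 114 ± 6.52 to 71.6 ± 3.27 kb. On chromosome 17 from 80131539 to 80335057, the siORCA to control ratio was 0.462 for BMI1, 0.501 for RNF2 and 0.843 for EZH2. On chromosome 13 from 111393683 to 111515247 it was 0.445 for BMI1, 0.535 for RNF2 and 0.682 for EZH2. The domain on chromosome 1 from 36734552 to 37009925 was covered almost by EZH2 alone, at 164 ± 19.6 kb in control and 92.3 ± 10.4 kb in siORCA libraries. On chromosome 8 from 85664923 to 86099723 EZH2 coverage overlapped between the conditions (282 ± 5.95 and 291 ± 22.96 kb), while BMI1 (281 ± 3.38 and 238.5 ± 4.90 kb) and RNF2 (321 ± 8.09 and 278 ± 18.3 kb) were lower. That domain lies in a stretch densely covered in all 12 lists, as does most of the chromosome 11 domain.

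**Figure D3:**
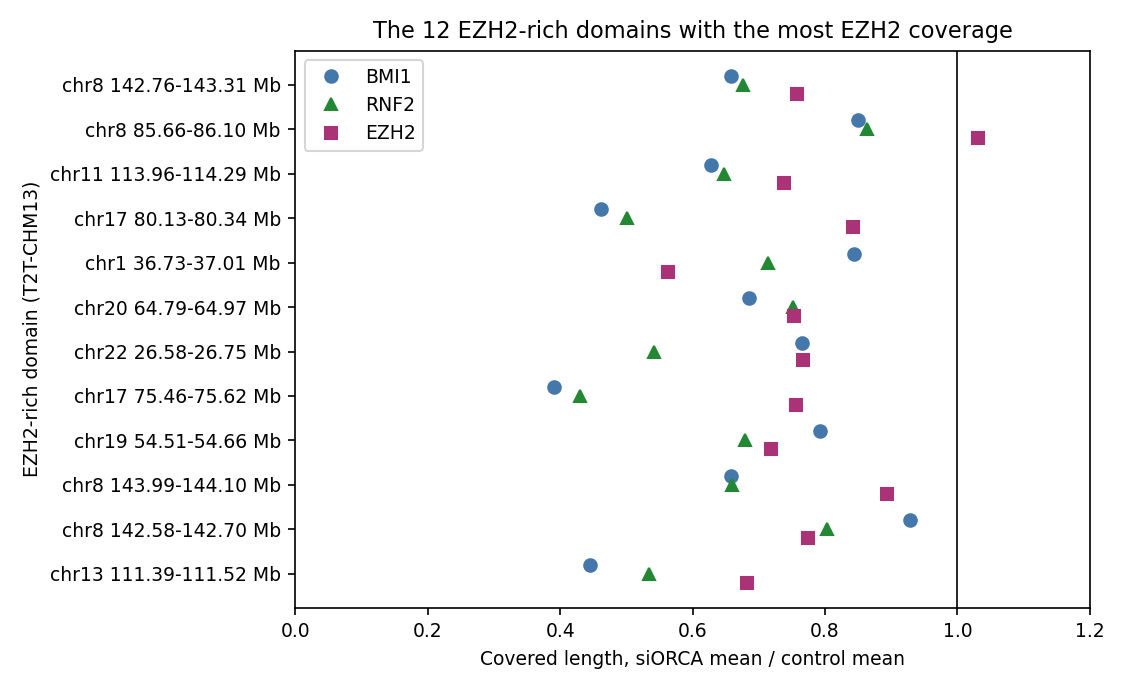
Ratio of mean covered length in siORCA to control libraries at the 12 EZH2-rich domains with the most EZH2 coverage, for BMI1 (circles), RNF2 (triangles) and EZH2 (squares). Values left of the line at 1 are lower in siORCA libraries; the domain on chromosome 8 from 85664923 to 86099723 has an EZH2 ratio of 1.03.

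Another 124 wide clusters spanning 5.95 Mb met the 25% minimum but were covered as much or more by the mean of BMI1 and RNF2. BMI1 covered 5.09 ± 0.00250 and 5.01 ± 0.0637 Mb, RNF2 5.23 ± 0.0305 and 5.10 ± 0.0566 Mb, and EZH2 3.14 ± 0.175 and 2.97 ± 0.318 Mb. The mean change was -0.049 (log2; exact permutation test, two-sided, p = 0.259). With same-numbered libraries as pairs it was lower in 6 of 6 pairs (exact sign-flip p = 0.0312, the smallest 6 pairs can give). The change was -0.24 without the densely covered bins (exact permutation p = 0.00926), a setting added later, and -0.082 in equally long lists (exact permutation p = 0.0278). Single libraries moved it as well, to between -0.094 and -0.0024 with each left out in turn (EZH2 -0.19 to 0.036). Counted by cluster, BMI1 coverage was lower in both siORCA libraries at 40 of the 124 (32.3%) and higher at 33, and RNF2 coverage was lower at 57 (46.0%) and higher at 14. In the EZH2-rich domains the shares of lower domains were 30.4% for BMI1 and 42.4% for RNF2, so lower PRC1 coverage was about as frequent in both classes. EZH2 was lower at 44 of the 124 clusters (35.5%) and higher at 12, against 81.6% lower in the EZH2-rich domains, and another split of its libraries gave 49 clusters one way. All 3 proteins were lower at 27 clusters (21.8%, against 24.7%).

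The next comparison asked which regions were bound in both libraries of a condition and in neither of the other. For BMI1, 8084 regions were lost and 10228 gained in siORCA libraries, of 174971 regions with a peak in any library. For RNF2, 7931 were lost and 9354 gained, and for EZH2, 5921 were lost and 8796 gained. Splitting the 4 libraries by condition gave 18312 BMI1 regions present in both libraries of a side and absent from the other, against 4466 when split by replicate and 4474 when crossed. The RNF2 counts were 17285, 4760 and 4899, and the EZH2 counts 14717, 6548 and 6426. A single antibody has 3 such splits, and its exact permutation test cannot go below p = 0.333. The number of regions bound per library rose by 0.37 on the log2 scale over the 3 antibodies (exact permutation test, two-sided, p = 0.00926) and by 0.28 between batch 1 libraries. In equally long lists the order turned, with 9896 lost and 6421 gained for BMI1, 8166 and 6475 for RNF2, and 6110 and 4822 for EZH2.

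Several of the lost regions with the highest ranks of fold enrichment were shared by the PRC1 proteins. The leading lost region of BMI1, on chromosome 19 from 8785920 to 8786386, had folds of 13.7 and 17.8 over local background in the control lists. RNF2 lost the same place (8785765 to 8786557), with folds of 24.4 and 18.98. A region on chromosome 6 was lost for BMI1 (161934797 to 161935194, folds 12.9 and 12.1) and for RNF2 (161934773 to 161935185, folds 15.8 and 11.8). On chromosome 5 both proteins gained a region, from 47298178 to 47298865 for BMI1 (folds 17.0 and 18.7 in the siORCA lists) and from 47298112 to 47298840 for RNF2 (folds 18.9 and 18.1). The leading lost EZH2 region lay on chromosome 19 from 8853112 to 8853697 (folds 23.2 and 20.5), and the leading gained EZH2 region on chromosome 1 from 130649319 to 130649838 (folds 9.13 and 10.1). Of the 10 leading regions kept in all 4 libraries, 9 for BMI1, 9 for RNF2 and 8 for EZH2 lay in the densely covered stretches. An example is chromosome 8 from 86885030 to 86886924 for EZH2. Of the 10 leading gained regions, 2 for BMI1, 5 for RNF2 and 4 for EZH2 lay in such stretches. Of the 10 leading lost regions, 3, 2 and 4 did. Repeats were not annotated here, so lost or gained regions in repeats were not told apart from others.

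The PRC1 proteins shared most of their reproducible regions, and EZH2 shared fewer. In control cells 80.6% of 38075 BMI1 regions overlapped an RNF2 region (exact 95% interval 80.2 to 81.0), and in siORCA cells 73.5% of 39850 did (73.0 to 73.9). Of EZH2 regions, 31.5% overlapped BMI1 in control and 32.4% in siORCA cells, and 33.7% and 33.0% overlapped RNF2. These intervals cover counting error only. Per library, the share of peaks that overlapped a reproducible region of the other antibodies was 60.03 ± 2.68% and 45.7 ± 8.91% for BMI1, 46.6 ± 3.91% and 40.4 ± 0.204% for RNF2, and 16.7 ± 2.06% and 15.9 ± 0.905% for EZH2. The mean change was -7.09 percentage points (exact permutation test, two-sided, p = 0.0278) and -4.92 between batch 1 libraries. With same-numbered libraries as pairs, p was 0.0625. Leaving out any of the 6 siORCA libraries ended the call, with changes from -1.68 points without siORCA BMI1 replicate 2 to -4.54 points without siORCA EZH2 replicate 1. A single library then defines the regions of its condition, and the changes per antibody ranged from -22.05 to -5.07 points for BMI1, -15.0 to 4.99 for RNF2 and -4.86 to 4.91 for EZH2 over all left-out libraries, so only BMI1 kept its direction.

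BMI1 regions lost after ORCA knockdown overlapped RNF2 regions more often than gained ones did, at 67.2% of 8084 against 52.0% of 10228 (odds ratio 1.90, Fisher's exact test, adjusted p = 1.53e-96). RNF2 regions showed a smaller difference with BMI1, at 44.5% of lost and 40.1% of gained regions (odds ratio 1.196, Fisher's exact test, adjusted p = 2.02e-08). EZH2 regions overlapped BMI1 at 23.4% of lost and 25.6% of gained regions (odds ratio 0.887, Fisher's exact test, adjusted p = 0.00442). With RNF2 they did so at 24.5% and 26.2% (odds ratio 0.913, Fisher's exact test, adjusted p = 0.0236). BMI1 regions overlapped EZH2 at 9.18% of lost and 10.2% of gained regions (odds ratio 0.888, Fisher's exact test, adjusted p = 0.0236). RNF2 regions did so at 9.51% and 9.29% (odds ratio 1.03, Fisher's exact test, adjusted p = 0.638). Regions are not independent replicates, so these p-values describe the lists. Gained regions come from the siORCA lists, which were longer, and the comparison was not repeated in equally long lists. Regions kept in all 4 libraries overlapped most, at 95.8% for BMI1 with RNF2. They were also wider, with a median of 1591 bp for BMI1, against 804 bp for lost and 790 bp for gained regions.

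Replicates were compared by the share of base pairs that their peaks had in common (Jaccard index). BMI1 control libraries shared 44.2%, siORCA libraries 33.7%, and libraries of different conditions 26.3 to 30.5%. For RNF2 the values were 44.0%, 39.2% and 30.2 to 33.9%. EZH2 lists were less alike, at 21.9% within control. The siORCA EZH2 libraries shared 13.1%, which lies within the 11.9 to 14.8% found between conditions. Regions called in a single library made up 84.3% of EZH2 regions, 63.8% of BMI1 regions and 60.7% of RNF2 regions.

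The distribution of peaks over chromosomes was examined after the data had been seen. The share of peaks was lower in siORCA libraries on chromosomes 1, 10, 12, 16, 17 and 19 and higher on chromosomes 2, 3, 4, 5 and 9, with an adjusted p of at most 0.0387 (exact permutation tests over 3 antibodies, Benjamini-Hochberg over 23 chromosomes). On chromosome 19, which is rich in genes, the share went from 2.64 ± 0.0119% to 1.93 ± 0.0697% for BMI1, from 2.81 ± 0.00589% to 2.32 ± 0.0998% for RNF2 and from 2.55 ± 0.225% to 1.94 ± 0.119% for EZH2 (adjusted exact permutation p = 0.0237). On chromosome 4, which is poor in genes, it went from 4.30 ± 0.112% to 5.31 ± 0.275% for BMI1, from 4.17 ± 0.0610% to 4.65 ± 0.125% for RNF2 and from 4.71 ± 0.328% to 5.71 ± 0.270% for EZH2. A trend with gene content was not tested, and these examples do not establish it. Some chromosomes had no common direction. On chromosome 20 the share rose for BMI1 (2.51 to 2.67%) and RNF2 (2.63 to 2.86%) and fell for EZH2 (3.65 to 3.09%). On chromosome 13 it fell for BMI1 (1.60 to 1.51%) and RNF2 (1.63 to 1.48%) and overlapped for EZH2. In all 3 antibodies both siORCA libraries lay on the same side of both control libraries for chromosomes 1, 2, 3, 4, 5, 9, 16, 17 and 19. With same-numbered libraries as pairs, no chromosome passed (smallest adjusted exact sign-flip p = 0.0653), although all 6 pairs agreed in direction on each of the chromosomes called above except chromosome 10.

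**Figure D4:**
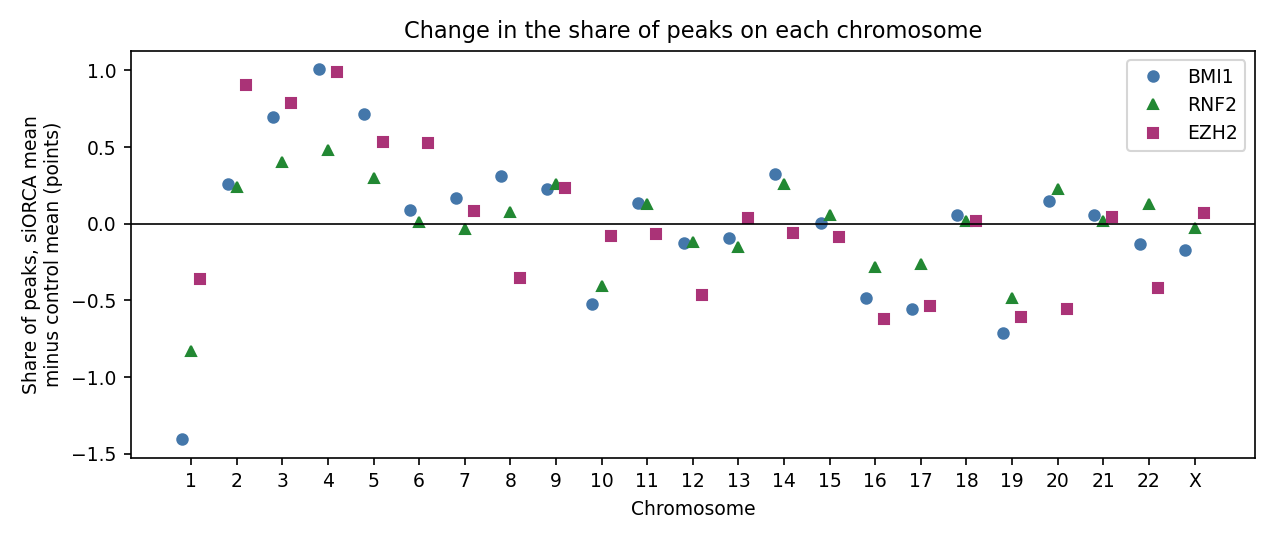
Difference between the mean share of peaks in siORCA and in control libraries, in percentage points, for each chromosome and antibody (2 libraries per condition). All 3 antibodies lie below 0 on chromosomes 1, 10, 12, 16, 17 and 19 and above 0 on chromosomes 2 to 6, 9, 18 and 21.

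In bins of 1000000 bp, also examined after the data had been seen, coverage was higher in both siORCA libraries for all 3 antibodies in 173 of 877 bins and lower in 52. The exact permutation p for the sum of 225 was 0.00926, and the highest count among other label splits, mirrors aside, was 79. The higher bins were most frequent on chromosomes 5 (24 bins) and 8 (21), and the lower ones on chromosomes 19 (8) and 8 (7). In equally long lists the balance turned, with 25 bins higher and 105 lower, and with a -log10 q of at least 5 there were 12 higher and 46 lower.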

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

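The EZH2-rich domains, the batch test and the tests on matched regions were chosen after the result had been seen, as were the chromosome shares below. The tests on regions outside the domains were set before their values were known.

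Results in which both siORCA libraries moved up for an antibody and down for another were picked out. The number of wide clusters changed by -0.62 (log2) for EZH2 relative to BMI1, and the number of peaks of at least 10000 bp by -1.04. For the share of peaks on a chromosome, the EZH2 change minus the BMI1 change was -0.663 percentage points on chromosome 8, -0.205 on chromosome 11, -0.386 on chromosome 14 and -0.705 on chromosome 20. The EZH2 change minus the RNF2 change was -0.197 points on chromosome 11, -0.321 on chromosome 14, -0.147 on chromosome 15, -0.779 on chromosome 20 and -0.546 on chromosome 22. The BMI1 change minus the RNF2 change on chromosome 22 was -0.260 points. Each difference had an exact permutation p of 0.0556 over 36 label splits, the smallest such a test can give, so none could pass 0.05. The rule that picked these results out fixed that p in advance, so it is no evidence for any of them.

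Lower coverage of EZH2-rich domains in siORCA libraries could come from a general loss of enrichment. For BMI1 and RNF2 the values argue against a loss of equal size in all regions. Regions called in all 4 libraries outside the domains and the densely covered bins changed by 0.02 and 0.0075 (log2), against -0.42 for both in such regions inside. These regions came from the full lists and were not matched for width or strength. They therefore cannot decide on a loss over wide clusters in general. Outside regions matched on covered length and fold rank changed by 0.21 for BMI1 and 0.086 for RNF2, against -0.45 and -0.55 for the regions inside. This match used the full lists, where all regions outside changed by 0.32 for BMI1 and 0.12 for RNF2. Longer siORCA lists could thus hide a loss, so the match cannot decide on a stronger loss of weak or narrow regions. For EZH2 both explanations stay open, since regions called in all 4 libraries changed by -0.29 outside and -0.46 inside, and matched regions by -0.36 outside, against -0.53 for the regions inside. Batch as the whole cause is argued against by the batch 1 libraries, where the least negative of the 3 changes was -0.46. An effect of the knockdown on PRC1 coverage of the EZH2-rich domains remains a hypothesis. It rests on the BMI1 and RNF2 values inside and outside the domains above, tested on the data it was found in and with no spike-in, and it does not extend to all wide EZH2 clusters, where BMI1 covered 10.3 Mb in control and 10.5 Mb in siORCA libraries. Nor is the frequency of lower PRC1 coverage particular to these domains, although the change in summed coverage was larger there. In the 124 other wide clusters with the 25% minimum, BMI1 was lower at 32.3% and RNF2 at 46.0%, against 30.4% and 42.4% of the domains. BMI1 was higher at 26.6% and RNF2 at 11.3%, against 14.1% and 13.3% of the domains. Summed coverage of these clusters changed by -0.024 for BMI1 and -0.036 for RNF2, against -0.46 and -0.55 in the domains. Without the densely covered bins, a setting added later, it changed by -0.22 for BMI1 and -0.24 for RNF2 (mean of 3 antibodies -0.24, exact permutation p = 0.00926). In control libraries BMI1 covered 5.09 of the 5.95 Mb that the 124 clusters span, against 2.31 of 20.1 Mb of the domains. Coverage near the full span can hide a lower signal, so the summed changes of the 2 classes are not like measures.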

How the results depend on the processing

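The definitions of the EZH2-rich domains, the chromosome and bin counts and the setting without densely covered bins were chosen after the data had been seen, and the other settings before. The increase in peak number kept its direction and its side of the threshold in every setting with a test, with 0.29 to 0.45 (log2) when each library was left out in turn (BMI1 0.19 to 0.68, RNF2 0.12 to 0.32, EZH2 0.31 to 0.59). The lower coverage of EZH2-rich domains did so in every such setting except 2 of the looser definitions of the domains, at -0.58 to -0.46 with each library left out. Counts of chromosomes with a changed share stayed within 1.5 times in every setting except the replicate block. What read depth limits could not be examined, because the lists give none. The cause of the changes below was not tested unless stated.

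With a -log10 q of at least 5, the change in covered length was 0.0096 (log2; EZH2 -0.16), in wide clusters -0.13 (EZH2 -0.72), in EZH2-rich coverage -0.73 for BMI1, -0.81 for RNF2 and -0.72 for EZH2, and in the other wide clusters -0.094 (exact permutation p = 0.0185). Lost and gained regions numbered 4986 and 5611 for BMI1, 5250 and 5588 for RNF2, and 1500 and 1119 for EZH2, as fewer peaks enter. Replicates exceeded other pairs by 11.6 Jaccard points for RNF2 and 7.04 for EZH2, and 12 bins were higher.

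In equally long lists, the change in covered length was -0.034 (BMI1 -0.0015, EZH2 -0.064), in wide clusters -0.21 (BMI1 0.059, RNF2 0.00011, EZH2 -0.69), and in regions bound -0.0014 (RNF2 -0.0075, EZH2 -0.0070), the last fixed by equal lengths. EZH2-rich coverage changed by -0.68 for BMI1 and -0.70 for RNF2, and the other wide clusters by -0.082 (exact permutation p = 0.0278). Gained regions numbered 6421 for BMI1 and 4822 for EZH2, with 25 bins higher and 105 lower.

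With same-numbered libraries as pairs (the replicate block), p was 0.0625 for covered length (0.21) and for overlap with other antibodies (-7.09 points), and 0.0312 for the other wide clusters (-0.049), all by exact sign flips. No chromosome share passed with the block (0 lower and 0 higher, smallest adjusted exact sign-flip p = 0.0653), because the smallest p that 6 pairs allow did not pass the adjustment over 23 chromosomes. The calls on peak number, wide clusters, regions bound, EZH2-rich coverage and bins (225, exact p = 0.0312) were unchanged by the block. In the 5 pairs of a shared batch and in batch 1 alone, which can reach no p under 0.05, RNF2 wide clusters changed by -0.069 and RNF2 coverage of EZH2-rich domains by -0.65. Without densely covered bins the other wide clusters changed by -0.24 (exact permutation p = 0.00926).

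With the EZH2 minimum at 50%, 142 domains were lower for EZH2 and 77 for all 3 proteins, out of fewer domains. With the 25% minimum alone, coverage changed by -0.15 for BMI1, -0.21 for RNF2 and -0.42 for EZH2. With the larger EZH2 share alone it changed by -0.040, -0.28 and -0.33, with a mean of -0.22. EZH2 coverage was lower at 866 clusters and higher at 736, and BMI1 coverage lower at 294 and higher at 608. Over all wide clusters it changed by 0.023, -0.087 and -0.26, with a mean of -0.11. EZH2 coverage was then lower at 976 clusters and higher at 872, and BMI1 coverage lower at 394 and higher at 805. All 3 proteins were lower at 208.

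Leaving out each library in turn gave 0.14 to 0.28 for covered length (BMI1 0.059 to 0.47, RNF2 -0.0020 to 0.18, EZH2 0.22 to 0.34), -0.0027 to 0.14 for wide clusters (BMI1 0.10 to 0.55, RNF2 0.029 to 0.34, EZH2 -0.43 to -0.16), -11.3 to -1.68 points for overlap with other antibodies (BMI1 -22.05 to -5.07, RNF2 -15.0 to 4.99, EZH2 -4.86 to 4.91), -0.094 to -0.0024 for the other wide clusters (EZH2 -0.19 to 0.036), and -0.64 to -0.41 for EZH2 coverage of EZH2-rich domains. The other wide clusters passed the threshold without siORCA EZH2 replicate 1 (exact permutation p = 0.00926). Lost regions ranged from 8084 to 28332 for BMI1, 7931 to 35726 for RNF2 and 5921 to 55359 for EZH2, and gained regions from 10228 to 64362, 9354 to 43485 and 8796 to 76728, since a single library then stands for a condition. The excess of replicates over other pairs ranged from 5.04 to 17.7 Jaccard points for BMI1, 6.66 to 13.2 for RNF2 and -0.63 to 9.57 for EZH2, the last negative without control EZH2 replicate 2. The promoter, gene list and sequence settings were not run, and using all sequences in the files moved nothing, because the lists hold no others.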

Other observations

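The chromosome shares and the test on gained EZH2 regions were chosen after the data had been seen, and the test of equally long lists for the chromosome shares was set before its value was known.

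Some of the widest clusters were covered alike in all BMI1 and RNF2 libraries. On chromosome 17 from 22284702 to 22501934, BMI1 and RNF2 peaks spanned all 217 kb in each library, and EZH2 covered 138 ± 7.37 kb in control and 132 ± 12.9 kb in siORCA libraries (n = 2 each). On chromosome 1 from 126688438 to 126964907, BMI1 covered 271 ± 0.225 kb in control and 271 ± 1.04 kb in siORCA libraries. On chromosome 8 from 86942856 to 87254198, BMI1 covered 261 ± 5.53 and 231 ± 7.79 kb, whereas EZH2 covered 235 ± 6.24 and 239.6 ± 17.2 kb.

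The shift of peaks between chromosomes may reflect weak peaks near the threshold, which are more numerous in the longer siORCA lists. Longer lists as the whole cause are argued against, because in equally long lists the change in the share on chromosomes 3, 4 and 5 together was at least 0.728 times that with full lists. For BMI1 it was 2.42 points with full and 1.76 with equal lists, for RNF2 1.18 and 0.883, and for EZH2 2.31 and 2.09. Equal length does not remove weak peaks. The full list of control EZH2 replicate 1 sets that length, and 22.8% of its peaks had a -log10 q of at least 5. Weak peaks as such therefore stay open as a cause. A loss of enrichment in gene-rich stretches and a redistribution after ORCA knockdown both stay open too, as untested.

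EZH2 regions gained in both siORCA libraries could be chance agreement of weak peaks, since these libraries were no more alike than libraries of different conditions. The siORCA lists are longer, which raises chance agreement between them, so the counts were compared in equally long lists. There 4822 regions were gained, 1.80 times the larger count among mixed pairs of a control and a siORCA library (2087 to 2678), which argues against chance as the whole cause. The 6110 regions lost outnumbered them, so an excess of gained over lost regions did not hold at equal length. With a -log10 q of at least 5 the number gained was 1119, below the 1500 lost.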
